A study of Drosophila melanogaster with 3 samples.

How the data were processed

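The samples were 3 biological replicates of whole embryos, 0 to 24 h old and of pooled sexes, from a line with a C-terminal GFP fusion of CG12104. Per the labels, chromatin was fragmented by sonication to 200 to 800 bp and precipitated with an antibody against GFP. All 3 samples formed 1 group, with the replicate numbers of the labels. The replicates were separate biosamples of the same line, so the spread between them covers embryo collection and library preparation but not other lines. No 2 replicate lists shared a region with identical coordinates. Their median region widths differed (460, 416 and 404 bp), so this says little about whether the libraries are distinct. Control alignments, untagged embryos and read-level files were not analysed here.

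The authors deposited lists of regions in 2 genome builds, dm6 and dm3. Per the deposited text lists that accompany the peaks, the regions of each replicate were called on that replicate against 1 control alignment, the pooled list on the 3 replicates together, and the IDR set was derived from these lists. The aligner, the peak caller and their versions are not given in the sources used here. Each region has a signal value, computed by the authors' peak caller on the scale of its own list and not scaled between replicates. Signal was therefore used only to rank or describe regions within a list, and replicates were compared by rank or by ratios within a replicate. Each region also has the -log10 of a q value, deposited by the authors. The candidate lists are permissive by this value: the highest q was 0.96 in the pooled dm6 list and 0.0152 in the IDR set. The IDR set was found to equal the 4060 regions with the highest signal of the pooled dm6 list, so a single signal minimum of 105.9 separates it from the rest. The 3 replicate lists in dm6 hold 30000 regions each, an equal size that points to a fixed maximum. Because the lists give no read counts, depth is unknown and no interval here covers it. Wilson intervals (95%) over peaks or genes cover counting error only, and the limit for a count of 0 is 3 counts of the total.

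Coordinates are 1-based and in dm6. Genes, exons and start sites were taken from the Ensembl BDGP6 annotation and sequence from the matching NCBI Release 6 assembly; the ends of all dm6 regions lay within its chromosomes. Where a region is given in a gene, its summit decided the class, in the order promoter (within 500 bp of a protein-coding TSS), 5' UTR, coding exon, 3' UTR, intron, other gene and intergenic. No annotation of dm3 was used, so the dm3 lists served only for counts, overlaps, correlations and shares per chromosome.

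Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Overlap of at least 1 bp between the 4060 highest regions of 2 replicates was set against 100 shuffles within chromosomes. Each IDR peak took the signal and rank of the highest overlapping region in each replicate. The share of summits near a TSS was set against 1000 random placements within chromosomes, and the numbers of peaks per arm against 10000 random placements by length. For 24 gene lists, genes with an IDR summit within 500 bp of a TSS were counted among members and among all other protein-coding genes on chromosomes with peaks, with two-sided Fisher's exact tests and Benjamini-Hochberg adjustment over the lists. The lists covered cytoplasmic and mitochondrial ribosomal proteins, translation factors, the proteasome, general transcription machinery, cell cycle, chaperones, histones, Polycomb and trithorax, insulators, Hox, segmentation, dorsoventral, early zygotic, Enhancer of split, neural, muscle, gut and fat body, cuticle, chemosensory, chorion and yolk, immune, ecdysone and HMG-box genes. For 38 consensus motifs, windows of 100 bp to each side of the summit were set against 2 windows centred 1000 bp away, by the same test; CACCTG and CAGGTG are the same word on opposite strands. All 7-base words were then scanned in a random division of the peaks into a search set and a check set of 2030 each.

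The genes named were fixed by rule before the data were examined. They are CG12104; the genes with a TSS within 500 bp of the 15 TSS-proximal IDR peaks with the highest signal; the nearest gene of the 10 highest distal peaks; up to 4 bound members with the highest signal for each list past the threshold and for the Hox, segmentation and HMG-box lists; and arms and motifs past the threshold of 0.05. An item that this rule names is not reported here. *Cp190*, the pairs at shared promoters and the members named in the closing section were added after their values were seen.

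The tests were tried on simulated data. With 40% of the mitochondrial ribosomal protein genes bound and all other genes at the observed rate, the list test called that list in 74% of 50 simulations, and called other lists in 0.174% of tests. With 40% of the 30 Polycomb and trithorax genes bound, it called that list in 42% of simulations, so short lists have little power. TATCGATA planted in 3% of 4060 random windows was called, with 0 of the 36 unrelated motifs called. In the 7-base search 1 unrelated word of 8192 was called. The simulated peak and background windows had the same base composition. These counts therefore give no rate of false calls for summits against flanks, which differ in GC content. The overlap counts equalled those of bedtools 2.31.1 for 5000 regions.

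Alternatives fixed beforehand were the 2030 IDR peaks with the highest signal, IDR peaks held by 2 of the replicates without regard to the other, the dm3 lists, other overlap rules, TSS windows of 200 and 1000 bp, nearest-TSS assignment within 5 kb, rotation of bound genes along the genome, and other motif windows and backgrounds. Added after seeing the data were GC-matched windows (2 per peak, same arm, within 1 percentage point of GC), genes with no other TSS within 1 kb, distal peaks alone with and without random distal positions as background, pooled regions as background, the chromosome test without the Y chromosome, and every alternative for the ratio of promoter to distal signal (the 2030 highest peaks, windows of 200 and 1000 bp, and without each replicate).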

Results

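Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map genomic regions bound by CG12104 in whole fly embryos. CG12104 is listed here with the HMG-box genes, whose products bind DNA through a high mobility group domain. The embryos were of mixed sex, 0 to 24 h old, and came from a transgenic *Drosophila melanogaster* line that makes CG12104 with GFP fused to its C-terminus. The fusion protein was precipitated with an antibody against GFP. The series holds 1 group of 3 biological replicates, so the comparisons lie between replicates, between classes of sites and between groups of genes. The reproducible set, selected by the authors by the irreproducible discovery rate (IDR), held 4060 peaks in the dm6 build and 3000 in dm3. In dm6 the list from the pooled replicates held 26959 candidate regions and each replicate's list held 30000. These lists carry no read counts, so the depth of each library is unknown.

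The gene of the tagged protein itself had a peak at its start site. CG12104 (FBgn0035238) lies on the minus strand of 3L from 1600726 to 1602674, and an IDR peak at 3L 1602596 to 1603045 covered its start site. The summit, at 1602821, lay at -147 bp from the CG12104 start site and at -133 bp from that of the divergent neighbour CG18170. This peak ranked 501 among all IDR peaks, with a pooled signal of 355.7, and the matching region ranked 322, 748 and 599 in replicates 1, 2 and 3. A stronger peak lay in an intron of CG13917, at 3L 1591791 to 1591977, with a pooled signal of 529 and ranks of 185, 263 and 184 in the replicates. The locus held 4 IDR peaks within 20 kb, against a median of 2 per protein-coding gene, and 21.7% of the 13945 genes had as many. Whether the transgene adds copies of this locus to the genome is not given in the sources used here, and its effect on the signal and ranks at CG12104 was not tested.

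**Figure D1:**
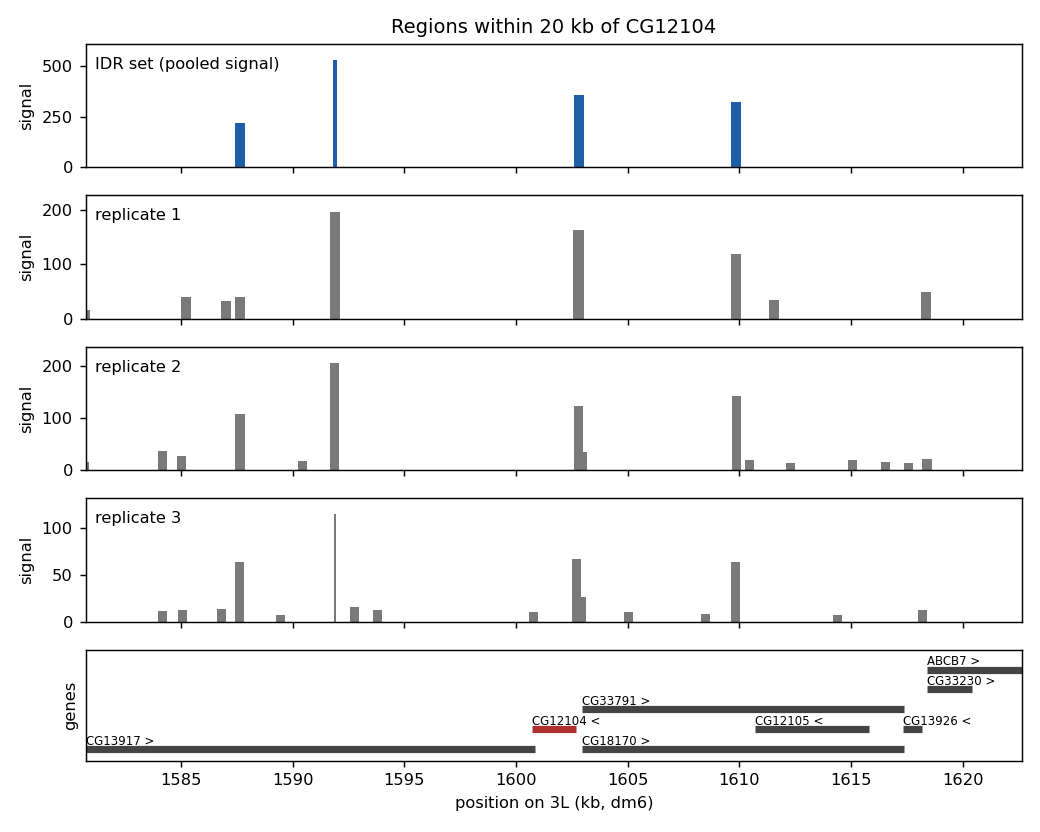
Regions within 20 kb of CG12104 on 3L (x axis, position in kb, dm6) with the authors' signal value (y axis, a separate scale per list) in the IDR set and in each replicate's candidate list, with gene bars carrying their strand as > or < and CG12104 in red. The peak at the CG12104 start site has ranks of 322, 748 and 599 in replicates 1, 2 and 3, and the weakest of the 4 IDR peaks, at 1587423 to 1587872, has 5091, 939 and 652.

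The 3 replicates were compared to learn how far their strongest sites coincided. The largest peaks were shared throughout: the strongest IDR peak, in an intron of CG11050 at 2L 6612478 to 6612908, ranked 1, 1 and 2 in replicates 1, 2 and 3, and the peak at the *Ugalt* promoter ranked 5, 2 and 1. Of the 4060 regions with the highest signal in each replicate, 75.3% ± 2.86 (SD over 3 pairs of replicates) overlapped a top region of the other replicate by at least 1 bp. Every pair exceeded all 100 shuffles of the regions within their chromosomes (permutation p = 0.0099, the smallest these can give). The IDR peaks overlapped a top region in replicate 1 in 83.5% of cases, in replicate 2 in 89.0% and in replicate 3 in 83.4%, and 2696 of them did so in all 3. Across peaks, which are not independent replicates, the signal of 2 replicates correlated with a Spearman rho of 0.709 for replicates 1 and 2, 0.664 for 1 and 3, and 0.783 for 2 and 3.

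The position of the peaks relative to genes was examined next. IDR summits were in excess at promoters and nearly absent from coding exons outside the promoter windows. Of the 4060 IDR summits, 2040 lay within 500 bp of the transcription start site (TSS) of a protein-coding gene, a share of 50.2% (95% Wilson interval 48.7 to 51.8), while random positions on the same chromosomes gave 11.5%. In each replicate's own top regions the share was 49.3% ± 5.55 (SD, n = 3). Introns held 1408 summits (34.7%, random 39.1%) and intergenic sequence 482 (11.9%, random 28.1%). The promoter class was assigned first, so its excess lowers the share left for every later class. Introns held 1408 of the 2020 summits outside promoters, so their lower share of all summits does not show a depletion. Coding exons outside the promoter windows held 8 summits, or 0.197%, against 13.9% of random positions. The excess at promoters exceeded all 1000 random placements (one-sided permutation p = 0.001, the smallest these can give).

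Within promoters most summits lay upstream of the nearest start site. Of the 2040 TSS-proximal summits, 1737 (85.1%, Wilson interval 83.5 to 86.6) lay upstream, and the median position was -123 bp (quartiles -224 and -49 bp). The median distance is shorter than the smallest fragments (200 bp), so the side of a single summit is poorly resolved. This share was not set against random positions near start sites. The other 2020 peaks lay a median of 2800 bp from the nearest TSS, and 667 of them lay beyond 5 kb. The candidate regions of the pooled list outside the IDR set were near a TSS less often, 22.1% of 22899 (Fisher's exact test, two-sided p = 5e-277).

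**Figure D2:**
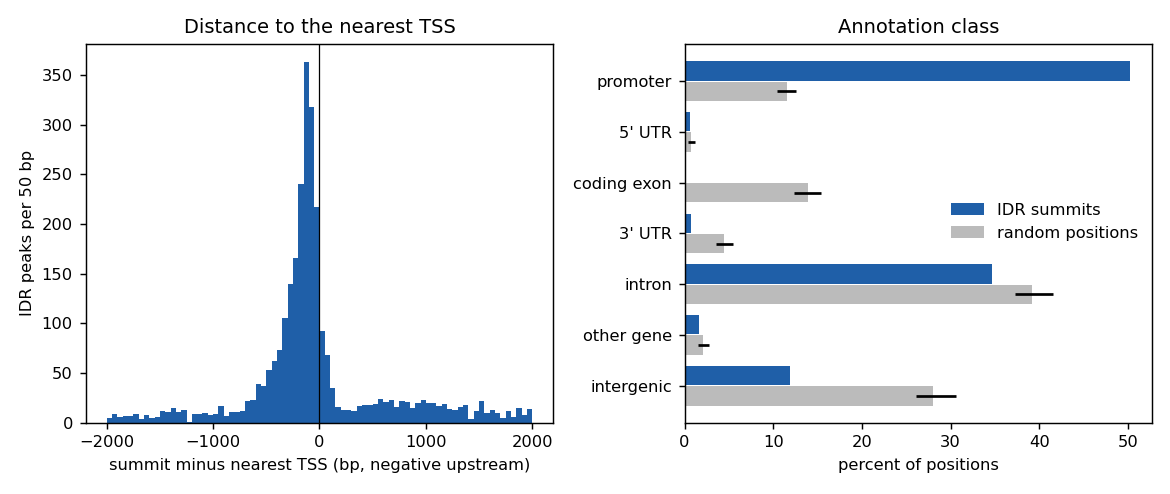
Left, number of IDR peaks per 50 bp (y axis) by distance of the summit from the nearest protein-coding TSS in bp (x axis, negative upstream), and right, percent of IDR summits (blue) and of random positions (grey, mean with the lowest and highest of 100 placements) in each annotation class. Promoters hold 50.2% of summits and coding exons 0.197%.

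Promoter peaks carried more signal than distal peaks in 2 replicates. The median signal was 1.30 times that of distal peaks in replicate 1 and 1.10 times in replicate 2 (permutation p = 0.0002 in each, the smallest 5000 permutations can give). In replicate 3 the ratio was 1.02 and did not pass the test (permutation p = 0.424). The mean ratio was 1.14 ± 0.142 (SD, n = 3). All 3 ratios lay above 1, where an exact sign test cannot give a p below 0.25.

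The strongest promoter peaks lay at genes of varied function. *Ugalt*, a UDP-galactose transporter gene, had the highest pooled signal among them, 1897, at X 2703685 to 2704098, with the summit at -47 bp from the TSS. CG14100 followed with 1829 at 3L 19590432 to 19590813. The wing vein gene *px* had 1530 (2R 22514136 to 22514489). The mitochondrial ribosomal protein gene *mRpL41* had 1490 (2R 15217582 to 15217924). Of these 15 peaks, 5 lay within 500 bp of the start sites of a pair of genes. These pairs were *Art3* and *mRpS10* (signal 1437), *Ssl1* and *Chro* (1320), CG11309 and CG7632 (1097), *Fbw5* and CG9147 (1085), and *CHMP2B* and *Tcs5* (1053). *Ssl1* encodes a subunit of the transcription factor TFIIH and *Chro* the chromatin protein Chromator. The remaining peaks were at CG18549 (1243), *SLC5A11* (1209), *Fkbp14* (1149), the Polycomb group gene *ph-p* (1120), CG31145 (1083) and the glycolytic gene *Gapdh2* (1044). In the replicates these 15 peaks ranked between 1 and 46.

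The strongest distal peak was that in CG11050 (signal 2158). The next was in an intron at -1362 bp from a *cbt* start site (1699, 2L 480886 to 481267); *cbt* encodes a zinc finger transcription factor. A peak 1530 bp into *Trl*, the gene of the GAGA factor, had a signal of 1457 (3L 14759300 to 14759718, intron). The HMG-box gene *HmgZ* had an intronic peak at -563 bp from a start site (1173, 2R 21703234 to 21703653). Intronic peaks also lay nearest to the kinase genes *Lk6* (1221) and *Tlk* (1029) and to CG32772 (1292). The peaks nearest to *hll* (1419) and CG4004 (1594) lay in other annotated genes, at -2912 and 5004 bp from those start sites. The peak nearest to CG13323 (1040) was intergenic, at a distance of 11970 bp. These 10 distal peaks ranked between 1 and 39 in the replicates.

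Gene groups fixed beforehand were compared to ask which kinds of promoter had peaks. A gene with an IDR summit within 500 bp of a TSS is called bound, which does not tell binding from unspecific enrichment. Ribosomal protein genes stood out. Of 86 genes for cytoplasmic ribosomal proteins, 64 had an IDR summit within 500 bp of a TSS (74.4%, Wilson interval 64.3 to 82.5), against 18.4% of other protein-coding genes. The odds ratio was 12.9 (two-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 7.6e-28 over 24 lists). The share in the replicates' own top regions was 75.6% ± 2.01 (SD, n = 3), higher than other genes in 3 of 3. Strong peaks among these were at *RpS27* (signal 847, 3R 25247383 to 25247701), *RpL7* (749) and *RpL13A* (585).

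Mitochondrial ribosomal protein genes were bound in 32 of 73 cases (43.8%, odds ratio 3.41, adjusted p = 4.6e-06; 37.0% ± 8.22 in the replicates, SD, n = 3, higher than other genes in 3 of 3; Fisher's exact test). Behind *mRpL41* and *mRpS10* came *mRpS23* (984) and *mRpL23* (907). This call ended when each peak was assigned to its nearest TSS, which gave 19.2% against 18.5% of other genes (exact adjusted p = 1). Without replicate 3 the share was 23.3% against 14.6% of other genes (odds ratio 1.77, exact test, adjusted p = 0.138). The 2030 peaks with the highest signal gave 20.5% against 11.0% (odds ratio 2.09, exact adjusted p = 0.0698). Genes with no other TSS within 1 kb were a setting chosen after seeing the data. There 1 of 13 members was bound, 7.69% (Wilson interval 1.37 to 33.3) against 9.53%, too few members to tell. The general transcription machinery, made up of RNA polymerase II subunits, TFIID and Mediator components and general factors, had 22 of 64 genes bound (34.4%, odds ratio 2.28, adjusted p = 0.0129; higher in 3 of 3 replicates, Fisher's exact test). The highest signals were at *Polr2B* (435), *Taf4* (371), *MED17* (362) and *MED27* (346). This call too ended with nearest-TSS assignment (18.8% against 18.5%, exact adjusted p = 1) and with the 2030 peaks of highest signal (20.3% against 11.0%, odds ratio 2.06, exact adjusted p = 0.0897). Among genes with no other TSS within 1 kb it ended as well. There 2 of 18 members were bound (11.1% against 9.52%, exact adjusted p = 0.863), too few to tell.

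Members of 4 lists had promoter peaks less often than other genes. None of 179 odorant, gustatory and ionotropic receptor genes had a promoter peak, which allows a share of up to 1.68% (exact adjusted p = 9.3e-16). Among 110 cuticle protein genes only *Cpr65Av* (signal 118) was bound (0.909%, odds ratio 0.0394, exact adjusted p = 2.7e-08). Of 34 neural genes only *elav* (623) was bound (2.94% against 18.8% of other genes, odds ratio 0.131, exact adjusted p = 0.0471). Without replicate 1, 2 or 3 the share stayed at 2.94% and that of other genes fell to 14.0%, 14.1% and 14.7%. The call then ended (exact adjusted p between 0.138 and 0.172). It also ended with nearest-TSS assignment (14.7% against 18.5%, exact adjusted p = 0.989), a 200 bp window (exact adjusted p = 0.0533), the 2030 peaks of highest signal (2.94% against 11.1%, exact adjusted p = 0.305) and rotation (permutation, adjusted p = 0.0631). In the replicates' own top regions the share was 7.84% ± 3.40 (SD, n = 3). None of the 112 genes on the histone list was bound, which allows up to 2.68% (exact adjusted p = 1.2e-09). All but *His4r*, a replacement histone gene, are replication-dependent and lie in repeated copies, where short reads cannot be placed with confidence. The call ended for the 27 list members with no other TSS within 1 kb, of which 0 were bound (exact adjusted p = 0.411). The shares of these 4 lists lay below those of other genes in 3 of 3 replicates.

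The lists of HMG-box, insulator, Polycomb and trithorax, Hox, segmentation and dorsoventral genes did not pass with peaks within 500 bp of a TSS. The HMG-box and Sox genes had 7 of 20 members bound (35%, odds ratio 2.34, exact adjusted p = 0.148), with the highest signals at *Sox14* (702), CG12104 (355.7), *Sox102F* (341) and *Hmg-2* (156). The insulator and architectural proteins had 6 of 14 (42.9%, exact adjusted p = 0.0785). The Polycomb and trithorax group had 10 of 30 (33.3%, exact adjusted p = 0.114). Of 8 Hox genes only *Dfd* was bound (signal 134; Fisher's exact test, adjusted p = 1). Of 29 segmentation genes only *bcd* (160) and *nkd* (147) were (exact adjusted p = 0.228). None of 21 dorsoventral patterning genes was, which allows up to 14.3% (exact adjusted p = 0.0664).

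Other settings called some of these lists. With nearest-TSS assignment within 5 kb, calls were made for muscle genes (15 of 32, 46.9%, exact adjusted p = 0.0011), Polycomb and trithorax genes (13 of 30, 43.3%, exact adjusted p = 0.0051), HMG-box genes (10 of 20, exact adjusted p = 0.0051) and Hox genes (5 of 8, 62.5%, exact adjusted p = 0.022). This test takes no account of how much sequence lies nearest each gene: against random distal positions, chosen after seeing the data, the distal peaks of these 4 lists did not pass (permutation test, adjusted p between 0.24 and 0.38). Their distal counts lay above the random means: 10 against 5.55 for muscle and 7 against 3.19 for Polycomb and trithorax genes. For HMG-box genes they were 6 against 2.29 and for Hox genes 4 against 2.01. The comparison leaves out the promoter peaks that nearest-TSS assignment includes, so it does not test those calls as a whole. Among genes with no other TSS within 1 kb, HMG-box genes were bound in 6 of 14 cases (42.9% against 9.46%, odds ratio 7.17, exact adjusted p = 0.0082). Without replicate 2 the insulator list passed (42.9%, odds ratio 4.60, exact adjusted p = 0.0286). It also passed in the top regions of replicate 1 (9 of 14, odds ratio 7.15, exact adjusted p = 0.0016) and replicate 3 (7 of 14, odds ratio 4.92, exact adjusted p = 0.0153). Polycomb and trithorax genes passed in replicate 3 (11 of 30, odds ratio 2.85, exact adjusted p = 0.034) and cell cycle genes in replicate 2 (14 of 42, odds ratio 2.46, exact adjusted p = 0.0393). With a 200 bp window translation factors passed (odds ratio 2.41, exact adjusted p = 0.0325), and with a 1000 bp window gut and fat body genes were called lower (3.33%, exact adjusted p = 0.037).

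The other lists did not pass the test with the 500 bp window. Cell cycle and replication genes were bound in 13 of 42 cases (exact adjusted p = 0.105), muscle genes in 9 of 32 (0.247), translation factors in 14 of 52 (0.228), heat shock genes and chaperones in 6 of 26 (0.736) and proteasome subunits in 10 of 48 (0.775). The shares were 4 of 11 for the Enhancer of split complex (0.228), 3 of 20 for ecdysone genes (exact adjusted p = 1), 5 of 34 for immune genes (0.759), 1 of 30 for gut and fat body genes (0.0785) and 1 of 17 for early zygotic genes (0.286). The list of chorion and yolk proteins had 1 of 18 (0.286), and that gene, *Cp190*, encodes an insulator protein and matched the list by its name alone.

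**Figure D3:**
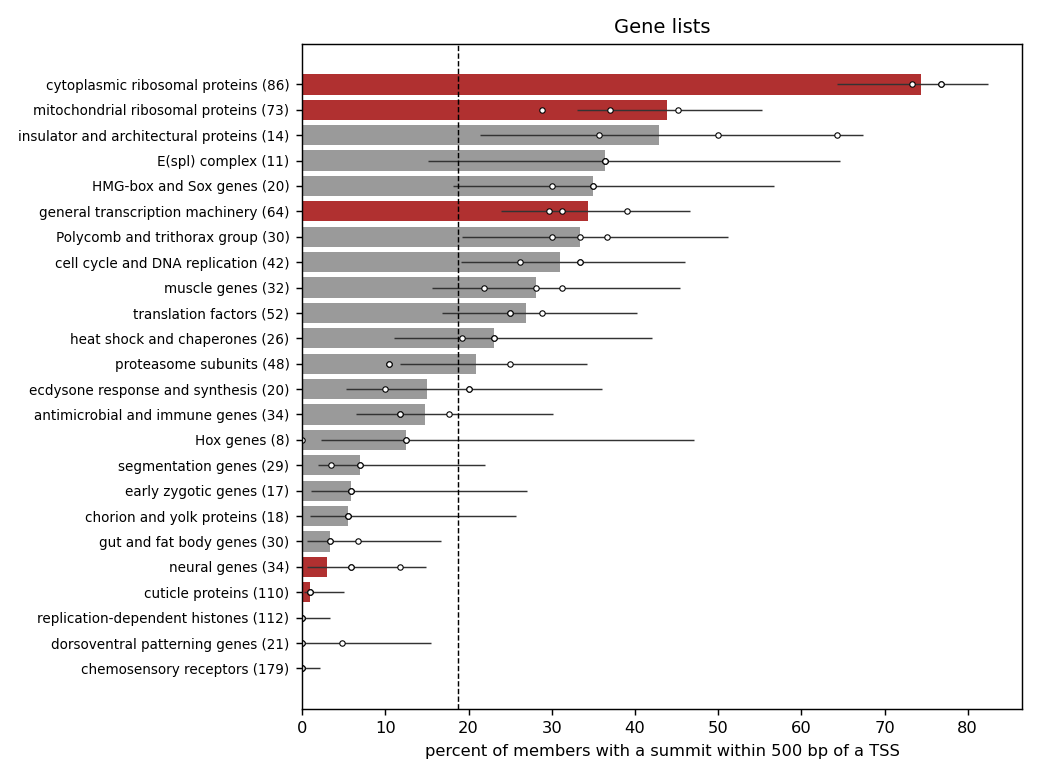
Percent of the members of each gene list with an IDR summit within 500 bp of a TSS (x axis; list size in parentheses), with 95% Wilson intervals, where open circles give the same share for the top 4060 regions of each of the 3 replicates, the dashed line marks all protein-coding genes (18.7%), and red bars passed an exact adjusted p of 0.05. Cytoplasmic ribosomal protein genes reach 74.4%.

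Peaks were sparse on the small chromosome 4, absent from the Y chromosome and similar in density on the 5 large arms. Chromosome 4 held 12 IDR peaks, or 8.90 per Mb, and the arms 2L, 2R, 3L, 3R and X held 31.8, 29.6, 31.8, 30.1 and 29.5 per Mb. The share of peaks on chromosome 4 was 0.296% (Wilson interval 0.169 to 0.516). In the replicates' top regions it was 0.345%, 0.271% and 0.271%. Of the 80 protein-coding genes on chromosome 4, 6 (7.5%) were bound at a promoter, against 18.8% elsewhere (odds ratio 0.350, Fisher's exact test, two-sided p = 0.00888). Among these peaks was that at *Sox102F*, at 4 807363 to 807812. The Y chromosome had no peak, which allows up to 0.0739% of peaks, and its repeats limit what can be mapped. The distribution over all 7 arms departed from arm length (permutation p = 1e-04, the smallest 10000 placements can give). Without the Y chromosome and chromosome 4 it did not (permutation p = 0.365).

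The sequence at the summits was compared with windows 1000 bp to either side. Peak summits were poor in G and C: windows of 100 bp to each side of the summit had a mean GC content of 34.5% ± 6.93 (SD over 4060 peaks), and flanking windows had 42.6% ± 9.51. In the replicates' top regions the mean was 35.03% ± 0.539 against 42.5% ± 0.294 (SD, n = 3). TSS-proximal summits had 34.1% and their flanks 44.7%, and distal summits had 34.9% and their flanks 40.5%.

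The DNA replication-related element TATCGATA (DRE), a core promoter element bound by Dref and BEAF-32, had the highest odds ratio of 38 fixed motifs against flanks, but not against GC-matched windows or unbound start sites. It occurred in 3.45% of summit windows and 0.616% of flanks (odds ratio 5.76, Fisher's exact test, adjusted p = 6.1e-29; 3.52% ± 1.03 against 0.620% ± 0.0432 in the replicates, SD, n = 3). The other core promoter elements Motif 1, GGTCACAC, which M1BP binds (2.12% against 0.628%, exact adjusted p = 6.3e-12), Motif 7 (11.3% against 5.87%, adjusted p = 8.8e-24) and Motif 6 (1.48% against 0.616%, adjusted p = 1.4e-05) were also more frequent. In distal peaks alone the DRE was found in 0.248% of windows and 0.619% of flanks (exact adjusted p = 0.136), and Motif 1 in 0.495% and 0.644% (adjusted p = 0.753). Against windows at the same distances from unbound start sites, TSS-proximal peaks had the DRE with an odds ratio of 1.98 (exact adjusted p = 4.4e-07), Motif 1 with 1.44 (exact adjusted p = 0.0358) and Motif 7 with 2.14 (exact adjusted p = 6.1e-20), and the call of Motif 6 ended (1.08, exact adjusted p = 0.818). Against flanks 12 motifs were more frequent and 9 less frequent at summits, with CACCTG and its reverse complement both counted.

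Motifs made mostly of A and T were more frequent at summits than in flanks. These included the TATA box (16.5% against 8.09%), the homeodomain word TAATTA (19.7% against 12.1%), the forkhead word (17.8% against 12.1%) and the HMG-domain word ATTGTT (25.5% against 19.96%, exact adjusted p = 2.2e-11). Against windows of matched GC content, a background chosen after seeing the data, ATTGTT was no longer enriched (25.5% against 25.1%, exact adjusted p = 0.736), nor were TAATTA (adjusted p = 0.552) or the TATA box (adjusted p = 0.0554). The DRE (odds ratio 4.17, exact adjusted p = 2.0e-22), Motif 1 (8.35, adjusted p = 2.0e-22), Motif 7 (2.64) and the forkhead word (1.36, adjusted p = 3.6e-08) kept their calls, and Motif 6 lost its call (1.34, exact adjusted p = 0.161). In this comparison 15 motifs were more frequent and 4 less frequent. Of the calls against flanks, 8 held in the same direction and 4 turned from lower to higher: CAGCTG (odds ratio 0.730 against flanks, 1.64 against matched windows), the CA repeat (0.713 and 1.31), the Mad and Brk word (0.535 and 1.36) and GCTGMG (0.662 and 1.23).

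An open search over 7-base words, with 2030 peaks for the search and the other 2030 for a check, called 960 words more frequent than in flanks, of which 687 passed in the check. The leading words held only A and T, such as TAAAATA (24.7% against 9.29% in the search peaks). Against windows of matched GC content 139 words passed both steps. The lowest p in the search peaks belonged to CAGTGTA, in 7.09% of search peaks against 1.60% of matched windows (odds ratio 4.69, exact adjusted p = 1.1e-22) and in 6.60% against 2.29% in the check (adjusted p = 4.1e-14). CACAGTG followed (6.70% against 1.798%, and 7.34% against 1.67% in the check), then ACAGTGG, with ATCGATA, the inner part of the DRE, next (7.93% against 3.03%). In the check peaks CACAGTG (odds ratio 4.65), ACTGTGC (4.59) and ACAGTGG (4.01) lay above CAGTGTA (3.01). Of the 139 words, 24 contained CACTG or its reverse complement, out of 48 such words among the 8189 tested.

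**Figure D4:**
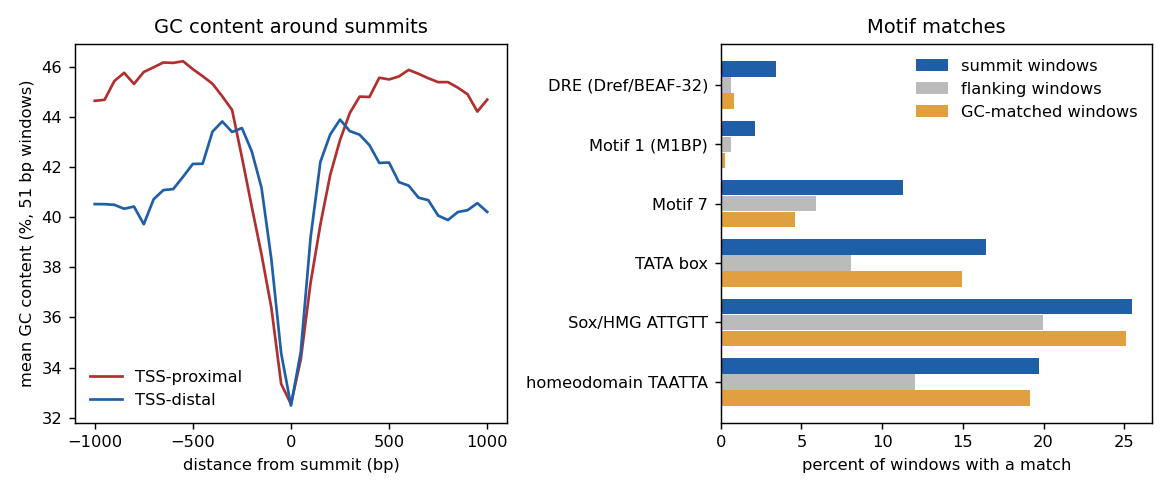
Left, mean GC content in percent (y axis, windows of 51 bp) by distance from the summit in bp (x axis) for TSS-proximal (red) and TSS-distal (blue) IDR peaks, and right, percent of windows with a match (x axis) to 6 motifs in summit windows, flanking windows and GC-matched windows; ATTGTT is at 25.5% in summit windows and 25.1% in GC-matched windows.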

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

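The dm3 lists of the replicates held regions on heterochromatic or unplaced scaffolds. The dm6 comparisons did not use these regions, while the dm3 overlap of top regions did not exclude them. Their numbers were 18 of 17996 in replicate 1, 30 of 16864 in replicate 2 and 61 of 29271 in replicate 3. They were noted because they lie outside the main measurement and above the 3 counts that a count of 0 allows. The dm3 IDR set had 0 regions there. No biological explanation was tested.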

How the results depend on the processing

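The GC-matched windows, the genes with no other TSS within 1 kb, both settings of distal peaks against gene lists, pooled regions as background, the test without the Y chromosome and all alternatives for promoter against distal signal were chosen after seeing the data. Among the main results, 54 values under alternatives kept their direction and their side of the threshold, or stayed within their spread or, for counts, within 1.5 times the main count, and 9 did not. Such a count does not say which lists or motifs passed. Nearest-TSS assignment called 8 lists, 4 of them among the 7 of the main setting, and distal peaks called 9, 3 of them shared, of which mitochondrial ribosomal proteins turned from higher to lower. GC-matched windows called 19 motifs, 8 shared in direction and 4 turned. The promoter share lay between 33.2% (200 bp window) and 59.9% (1000 bp window). Single items were counted only for the lists called in the main setting and for part of the motifs called more frequent at summits. The DRE, Motif 1 and Motif 7 were among these motifs. Motifs called less frequent at summits were not counted, which leaves out the 4 that turned against GC-matched windows. Of the values counted under alternatives, 96 kept their call, 24 kept their direction without passing the threshold and 11 reversed. The cause was not tested unless stated. Leaving out 1 replicate gave a rank correlation of 0.664 to 0.783. The IDR set has 2030 peaks when only those with the highest signal are kept, by construction. The number of lists past the threshold was 4 with those peaks, 4 among genes with no other TSS within 1 kb and 1 for distal peaks against random distal positions. The CG12104 locus held 9, 15 and 16 regions in the full lists of replicates 1, 2 and 3, which are permissive. With distal peaks only, 12 motifs passed, and the odds ratio reversed for the DRE (0.399), Motif 1 (0.768) and Motif 7 (0.804). None of these reversals passed the threshold (exact adjusted p = 0.136, 0.753 and 0.195). Among genes with no other TSS within 1 kb, 1 of 13 mitochondrial ribosomal protein genes was bound (7.69%, Wilson interval 1.37 to 33.3). That is too few to tell a reversal from no change. For distal peaks assigned to the nearest TSS within 5 kb, the share reversed for cytoplasmic (2.33%) and mitochondrial ribosomal proteins (0%). It also reversed for the general transcription machinery (0%) and neural genes (14.7%). Only the mitochondrial list passed there (exact adjusted p = 0.0282). The others did not (exact adjusted p = 0.197 for cytoplasmic ribosomal proteins, 0.0537 for the machinery and 0.142 for neural genes). Against random distal positions the share reversed for cytoplasmic (2.33%) and mitochondrial ribosomal proteins (0%) and the general transcription machinery (0%). None of these passed (permutation test, adjusted p = 0.767, 0.349 and 0.288). Depth is unknown, so no limit from it can be given.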

Other observations

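The tests of distal peaks near genes, of library composition, of GC content at the word CACTGAGA, of summit position at ribosomal protein genes and of active promoters were chosen only after results were seen. The word CACTGAGA was picked from a scan of the same peaks.

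Distal peaks were assigned to the nearest TSS within 5 kb and counted over the fixed gene lists. Of 8 Hox genes, 4 were the nearest gene of a distal IDR peak within 5 kb. These were *Abd-B* (signal 273), *abd-A* (140), *Antp* (133) and *lab* (112). Dorsoventral patterning genes had 7 of 21 such members, among them *sim* (603), *brk* (436) and *ush* (327). Polycomb and trithorax genes had 7 of 30, with *Trl* (1457), *Psc* (936), *trx* (681) and *ph-d* (623), and HMG-box genes had 6 of 20, with *HmgZ* (1173) and *Dsp1* (238). Against 1000 sets of random positions between 500 bp and 5 kb from a TSS, none of these 4 lists passed (permutation test, adjusted p = 0.38, 0.387, 0.288 and 0.24), nor did muscle genes with 10 of 32 (0.288). Each nevertheless lay above its random mean, which was 2.01, 4.22, 3.19 and 2.29 for these 4 lists and 5.55 for muscle genes. Enhancer of split genes (3 against 0.609, permutation test, adjusted p = 0.24) and cell cycle genes (7 against 3.38, adjusted p = 0.304) did so too. Ecdysone genes had 5 against 4.90, and all other lists lay below their random means. No list above its random mean passed. Segmentation genes (4 against a random mean of 5.26), neural genes (5 against 6.65) and early zygotic genes (2 against 2.68) had no more than random positions. The distal peaks reached 975 genes in all and the random sets a mean of 1233. Numbers below and above the random means are to be read against that, since it makes an excess harder to call. Chemosensory receptor genes, with 4 members against a mean of 15.9, had fewer (permutation test, adjusted p = 0.048), without allowance for this overall difference.

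Genes of other classes had peaks within 500 bp of a start site less often than protein-coding genes (18.7%). The numbers were 183 of 3261 noncoding RNA genes (5.61%), 9 of 290 tRNA genes (3.10%) and 13 of 269 snoRNA genes (4.83%). These shares were not set against random positions, so they do not show a depletion. Over 1 kb from a protein-coding start site the numbers were 88 of 2331 (3.78%), 3 of 211 (1.42%) and 4 of 184 (2.17%).

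Peak summits were poor in G and C. Position relative to the TSS is unlikely as the whole cause: TSS-proximal summits had 34.1%, their flanks 44.7% and windows at the same distances from unbound start sites 40.3%, so that a difference of -6.14 percentage points remained beside the part that goes with position. A composition bias of the libraries stays open, because no control library was analysed here. Between peaks and windows of the same GC content 19 of 38 motifs differed, but these also differ in promoter position, so the count decides nothing. No biological explanation was tested.

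The word CACTGAGA occurred in 135 IDR peaks (3.33%) and in 0.406% of flanks. It was found in 113 distal (5.59%) and 22 TSS-proximal peaks (1.08%; odds ratio 5.44, Fisher's exact test, p = 9.8e-17). GC content is an unlikely cause: in the 2030 check peaks of the 7-base search, its first 7 bases were 3.54 times as frequent as in GC-matched windows (exact adjusted p = 7.9e-14 over 195 words; 95% interval 2.57 to 4.88, which lies above the 1.5 set after seeing results but reaches below the 3 first set for the whole word). Copies of annotated transposable elements are unlikely too, as 0 of the 135 lay on a transposable element, which allows up to 2.22%, beside 0.197% of all summits. It may be part of a sequence bound by CG12104 or by a partner, which was not tested.

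Promoters of cytoplasmic ribosomal protein genes were bound more often than others. Promoters of neighbouring genes are an unlikely cause, since the odds ratio was 13.5 among genes with no other TSS within 1 kb. Signal spread over transcribed gene bodies stays open. It was taken to put at least as many summits downstream of the TSS as upstream. Of 64 summits, 89.1% lay upstream (Wilson interval 79.1 to 94.6). The lower end is below the 80% also written down for this test. The median summit lay at only -44.5 bp, a distance shorter than the smallest fragments (200 bp), so its side of the TSS is poorly resolved. Of all TSS-proximal summits 85.1% lay upstream too, so the share at these genes does not decide. Unspecific enrichment at active promoters cannot be told apart from binding, because no untagged immunoprecipitation was analysed here. Proteasome subunit genes were bound in 20.8% of cases, but that list also holds paralogues such as *Prosalpha3T* and *Rpt3R*. Which members are active in these embryos was not tested, so the share decides nothing.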
